A study of Arabidopsis thaliana with 8 samples.

How the data were processed

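RNA of whole Arabidopsis thaliana seedlings was measured on 8 Agilent oligonucleotide arrays with 45220 spots, scanned in 2 channels. Per the labels, 25 ng of RNA was labelled, Cy3 carried the phyB-9 mutant and Cy5 the transgenic line on every array, 4 with ML1pro:PHYBGFP/phyB-9 and 4 with PHYBpro:PHYBGFP/phyB-9, named here ML1pro and PHYBpro. No array has the dyes exchanged. The 4 arrays of a line shared 1 of 2 slides. The labels call the 4 arrays of a line biological replicates and state no pairing between the lines.

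Per the file headers, the values of each array are spot intensity values from Feature Extraction 11.5.1.1, as median signal and median local background in both channels, with no normalization. The same deposited files hold processed signals, intensity values that the scanner software corrected for background, spatial trend and dye. The authors also deposited a table for each line with a mean log2 intensity, a log2 ratio, a p-value and a false discovery rate per spot. For these tables the submitters' processing notes name limma and give no version, background or normalization. The authors' tables hold no values per array, so all values in the results come from the array files.

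Background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3 with version 1.17.8 of data.table, on median signals, because the files hold no mean signals, which the plan had named. Log2 ratios of Cy5 over Cy3 were normalised by loess within arrays, with no normalization between arrays. Of 43603 distinct probes 34348 (78.8%) were matched to 1 of 25410 loci through the sequence records the files name. Where a locus had more than 1 probe (6946 loci), the probe with the highest mean intensity was used. Genes were tested when this probe was well above background in at least 3 of the 4 arrays of 1 line in 1 channel, which left 20896 genes. Positions in the genome were not used. Precision is limited by the number of arrays.

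1 limma model with a coefficient per line was fitted to the 8 arrays (6 residual degrees of freedom, 3.93 prior), and p-values were adjusted by Benjamini-Hochberg over the tested genes at a threshold of 0.05. Changes of at least 2-fold are called genes with an absolute log2 ratio of at least 1. The difference between the lines is the contrast of both coefficients, ML1pro minus PHYBpro. For a gene not well above background in 1 of the groups, the fold is computed against the lowest level counted as above background and given as "at least". phyB-9 was compared between the slides on Cy3 log2 intensity after loess and quantile normalization of average intensity. PHYB was also compared by a two-sided exact permutation test over 70 splits, in 1 comparison for each of 3 quantities. The correlation of the lines was set against 79 random sign flips of the arrays' deviations from each gene's line mean.

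Fixed gene lists (23 lists, 363 genes, 351 of them tested) cover shade avoidance, auxin, SAUR genes, brassinosteroid, gibberellin, ethylene, chlorophyll, antenna, photosystem and Rubisco, photoreceptors, clock, flavonoids, expansins, starch, gravitropism, dark-inducible genes, defence and stress, markers of epidermis, endodermis, vascular tissue and root hairs, seed storage and reference genes. GH3.4, PRR9, FT, PAP2, MYB11, PR1, PR2, COR15A and SHN1 were too dim to test, and SAUR24, SOB7 and ACT2 matched no probe. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, with p-values adjusted over the 23 lists of a comparison, and with an exact permutation of the arrays' list means for the difference. With the preset correlation 10, 11 and 13 lists were called in ML1pro, PHYBpro and the difference, and 0, 0 and 0 with an estimated correlation. A list is said to be called only where camera at the preset correlation calls it. fry, which tests whether a list's genes move on balance 1 way and does not compare them with other genes, called 14, 19 and 14 lists. Named genes are PHYB, the 10 largest rises and falls per line and the 5 largest differences each way among called genes with a symbol and with arrays on 1 side, and list members in order of adjusted p, about 30 per comparison. PORB, as 1 of only 2 falling genes of its list, was named after its value was seen, and so were the genes whose values on ML1pro replicate 1 are given.

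The comparisons, tests, lists, naming rule and other settings to try were fixed before the data were examined. These settings changed the background correction (none, offset 16, processed signals), the normalization (median centring, quantile, equal spread of log2 ratios), the filter on dim probes, the choice of probe, the variance prior, a fit per line, a block of replicate numbers, single channels and the size at which genes were chosen, and left out each array in turn. Counting unmatched probes, and the effect size without ML1pro replicate 1, were added after seeing the data. The pipeline was tested on simulated data with 200 changed genes and an SD of 0.152 between arrays, which was that of the PHYBpro arrays and was used for both lines. No outlying array was simulated, so the rates for ML1pro and the difference do not cover the deviation of ML1pro replicate 1. A log2 change of 0.5 was found in 92% of genes in ML1pro, 94% in PHYBpro and 60% in the difference, and 0.17%, 0.22% and 0.01% of unchanged genes were called. Far more genes were called in the data (51.5% in ML1pro and 69.2% in PHYBpro), which loosens the Benjamini-Hochberg cutoff, and no dye bias of single probes was simulated. These rates therefore do not give the share of unchanged genes called in the data. A simulated ratio between the lines of 0.5 was recovered as 0.503.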

Results

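Transcript levels in whole seedlings of Arabidopsis thaliana were measured on 8 Agilent oligonucleotide arrays with 2 channels each. On every array a transgenic line, labelled with Cy5, was set against the phyB-9 mutant, labelled with Cy3. phyB-9 seedlings lack functional phytochrome B, the main photoreceptor of seedlings in continuous red light. Both lines carried a fusion of phytochrome B with the green fluorescent protein in this mutant. In the ML1pro line an epidermis-specific promoter drove the fusion (4 arrays), and in the PHYBpro line the promoter of PHYB itself did (4 arrays). Seeds were stratified for 3 days, exposed to white light for 6 h and kept for 4 days in red light of 11.4 µmol per square metre and second. The labels give 4 biological replicates per line and do not say whether these came from separate cultures, so p-values measure the spread between these samples.

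Between 75.9% and 78% of probes were well above background in Cy3 and between 72.9% and 75.4% in Cy5, with 0 saturated probes on each array, and 20896 genes were tested. Gene values below are mean log2 ratios of line over phyB-9 ± SD over the 4 arrays of the line, and the number of arrays limits their precision. ML1pro replicate 1 stood apart from the other arrays. Its log2 ratios had an SD across genes of 0.368, against 0.466 to 0.484 on the other ML1pro arrays and 0.642 to 0.69 on the PHYBpro arrays. Across genes they correlated with those of the other ML1pro arrays at r = 0.772 to 0.846, while other pairs of ML1pro arrays reached 0.968. This array is part of every ML1pro value given here unless the text says that it was left out. By regression, the authors' deposited ML1pro ratios gave it a weight of -0.001, against 0.333 to 0.334 for replicates 2 to 4. The 4 arrays of each line lay on a slide of their own, so line and slide cannot be told apart in a comparison of the lines.

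The PHYB transcript (AT2G18790), which both transgenes supply, was higher than in phyB-9 on all 8 arrays. Its log2 ratio was 1.70 ± 0.24 in ML1pro and 3.09 ± 0.14 in PHYBpro (SD, n = 4 each). The lines differed by -1.39, ML1pro minus PHYBpro (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give, limma adjusted p = 2.29e-05). The difference lay in the line channel, at a log2 intensity of 11.42 ± 0.04 in ML1pro and 12.92 ± 0.10 in PHYBpro (exact permutation p = 0.0286). The phyB-9 channel stood at 9.72 ± 0.21 and 9.83 ± 0.08 (exact permutation p = 0.371). It was 10.04 on ML1pro replicate 1, while the other ML1pro arrays (9.59 to 9.62) all lay below the PHYBpro arrays (9.76 to 9.93). The transcript was read by 1 probe whose place in the gene is not given in the sources used here, and phyB-9 itself gave signal at it. Scaling every array to the same spread of log2 ratios, which removes a difference in size between the lines by its construction, turned the difference to 0.23 (limma adjusted p = 0.864).

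**Figure D1:**
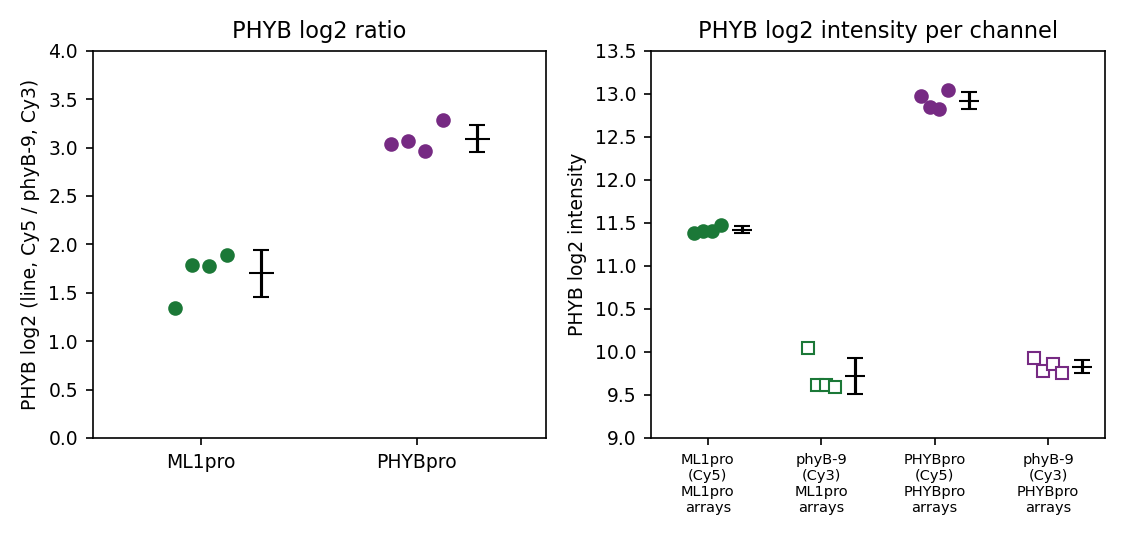
Left, the log2 ratio of PHYB (line over phyB-9) on each of the 4 arrays of ML1pro and PHYBpro, with mean and SD as bars; right, its log2 intensity per array in the line channel (filled circles, Cy5) and the phyB-9 channel (open squares, Cy3). The ML1pro ratios lie between 1.35 and 1.89 and the PHYBpro ratios between 2.97 and 3.28. The phyB-9 channels of both sets of arrays overlap only through ML1pro replicate 1 (10.04). The other ML1pro arrays lie at 9.59 to 9.62 and the PHYBpro arrays at 9.76 to 9.93.

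The comparison of ML1pro with phyB-9 asks which transcripts change when phytochrome B is returned under the epidermal promoter. All 21 light-harvesting antenna genes rose in ML1pro, with a list mean of 1.86 ± 0.18 (SD over arrays, n = 4, adjusted p = 0.347 with an estimated correlation), led by the chlorophyll-binding proteins LHCB1.4 (3.84 ± 0.23) and LHCB2.3 (3.15 ± 0.18). All 27 genes of photosystem subunits, electron transport and the Rubisco small subunit rose as well (mean 1.64 ± 0.17, adjusted p = 0.347 with an estimated correlation), among them the Rubisco gene RBCS3B (1.77 ± 0.13). Of 17 genes of shade avoidance or of induction by PIF transcription factors, 14 fell and 1 rose (mean -0.76 ± 0.04, adjusted p = 0.219 with an estimated correlation), with the cell wall enzyme gene XTH15 at -2.68 ± 0.15.

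At the preset correlation the antenna list had camera adjusted p = 2.9e-16, and the photosystem list camera adjusted p = 1.09e-18. Counts adjusted over the list alone stayed at 21 and 27 rising genes. The shade avoidance list had camera adjusted p = 1.23e-07, and adjusted over the list alone 15 of its genes fell. Of 23 genes of auxin synthesis and early auxin response, 17 fell (18 adjusted over the list alone) and 2 rose, with a mean of -0.45 ± 0.13 (camera adjusted p = 5.43e-06, adjusted p = 0.347 with an estimated correlation). Among them the Aux/IAA repressor gene IAA5 fell by 0.79 on the log2 scale. Of 15 SAUR genes, which auxin induces in elongating tissue, 8 fell and 2 rose, or 9 and 3 adjusted over the list alone, with a mean of -0.33 ± 0.23 and SAUR9 at -0.92 ± 0.20 (camera adjusted p = 0.0424, adjusted p = 0.781 with an estimated correlation). The SAUR call ended without ML1pro replicate 1 (mean -0.22, adjusted p = 0.153) and under 5 other settings (adjusted p = 0.0526 to 0.149, means of -0.74 to -0.29). Of 15 genes of ethylene synthesis and signalling 11 fell, the same number as adjusted over the list alone (mean -0.27 ± 0.06, camera adjusted p = 0.0173, adjusted p = 0.301 with an estimated correlation). Of the 2 that rose, EFE stood at 1.03 ± 0.32, a gene of the last step of ethylene synthesis.

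In chlorophyll and haem synthesis 14 of 21 genes rose (15 adjusted over the list alone) and 2 fell, with a mean of 0.34 ± 0.03 (camera adjusted p = 0.00114, adjusted p = 0.714 with an estimated correlation). The fallers were PORA (-3.16 ± 0.07) and PORB (-1.45 ± 0.14), which encode protochlorophyllide oxidoreductases, while CAO, which makes chlorophyll b, rose by 2.19 ± 0.13. Of 31 photoreceptor and light signalling genes 21 rose and 6 fell, with the same counts adjusted over the list alone (mean 0.57 ± 0.11, camera adjusted p = 0.000282, adjusted p = 0.459 with an estimated correlation). SPA1, a partner of the COP1 ubiquitin ligase, rose by 1.2 ± 0.07. In flavonoid synthesis 10 of 19 genes rose and 3 fell, also when adjusted over the list alone, without a camera call for the list (mean 0.26 ± 0.11, camera adjusted p = 0.085, adjusted p = 0.781 with an estimated correlation, fry adjusted p = 0.00268), although camera called it with processed signals (adjusted p = 0.0272) and without ML1pro replicate 3 (0.0351). The flavonoid glucosyltransferase gene UGT78D2 rose by 1.14 ± 0.08. Expansins and xyloglucan endotransglucosylases (mean -0.15 ± 0.16, 4 rose and 7 fell of 21, mean -0.07 without ML1pro replicate 1, camera adjusted p = 0.35, fry adjusted p = 0.862) and starch metabolism (mean 0.35 ± 0.06, 6 rose and 5 fell of 16, camera adjusted p = 0.588, fry adjusted p = 0.00186) had no camera call either. Adjusted over the list alone, these counts did not change. Scaling all arrays to the same spread of log2 ratios ended the call of the chlorophyll list (adjusted p = 0.0655) while its mean grew to 0.55, and moved the means of the antenna (2.89), photosystem (2.53), shade avoidance (-1.24) and auxin lists (-0.85). With processed signals the ethylene mean was -0.59. Among the uncalled lists the expansin gene EXPA1 rose by 1.97 ± 0.06 and the starch synthesis gene APL1 by 1.18 ± 0.09.

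Among genes with a symbol the largest rises in ML1pro were those of XTH6 (4.28 ± 0.82), a xyloglucan endotransglucosylase, COL2 (3.93 ± 0.15) and BBX16 (3.35 ± 0.80), B-box zinc finger factors, the clock gene LHY (3.32 ± 0.55) and the chloroplast beta-amylase gene BAM3 (3.24 ± 0.70). With LHCB1.4 and LHCB2.3 the 10 also held the NAD(P)H dehydrogenase gene NDA1 (3.54 ± 1.05), the thionin gene THI2.2 (3.24 ± 0.49) and the methionine sulfoxide reductase gene MSRB6 (3.12 ± 0.21). After PORA the largest falls among such genes were those of MYB10 (-2.78 ± 0.76), the calmodulin-like gene CML41 (-2.68 ± 0.83), XTH15, FAR1 (-2.41 ± 0.06), a fatty acyl reductase gene, and GRF7 (-2.33 ± 0.58). FAR8 (-2.23 ± 0.27), also a fatty acyl reductase gene, the Aux/IAA gene IAA20 (-2.07 ± 0.31) and the bHLH gene HEC2 (-2.01 ± 0.06) followed. The B-box gene bbx23, not well above background in ML1pro, was at least 3.72-fold lower than in phyB-9 (limma adjusted p = 0.000459). On ML1pro replicate 1 the values of NDA1 (1.99), BBX16 (2.16), MYB10 (-1.65), CML41 (-1.45) and bbx23 (-0.33) lay closer to 0 than on the other 3 arrays.

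In all, 10759 of 20896 genes (51.5%) differed between ML1pro and phyB-9 by limma at an adjusted p below 0.05, of which 5552 were higher and 5207 lower. At least 2-fold changes numbered 843, with 699 higher and 144 lower, and 997 without ML1pro replicate 1. Of the called genes 51.6% were higher, against 39.9% with the scanner software's processed signals, which also gave 1736 changes of at least 2-fold, and scaling all arrays to the same spread gave 1620. Those at least 2-fold lower then numbered 626 and 452, and 229 without background subtraction. All arrays carried the line in Cy5, so a probe's dye bias is part of each ratio, and near-identical members of the LHCB1, LHCB2, Rubisco and SAUR families can share signal between their probes.

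The comparison of PHYBpro with phyB-9 asks the same of phytochrome B under its own promoter. All 17 shade avoidance genes fell in PHYBpro (list mean -1.77 ± 0.07, SD over arrays, n = 4, adjusted p = 0.0652 with an estimated correlation), with PIL1, a bHLH gene that shade induces, at -3.82 ± 0.05. All 15 SAUR genes fell (mean -2.08 ± 0.24, adjusted p = 0.385 with an estimated correlation), including SAUR22 (-3.74 ± 0.24). Of 23 auxin genes 20 fell and 2 rose (mean -1.23 ± 0.06, adjusted p = 0.308 with an estimated correlation), including IAA19 (-3.73 ± 0.23), IAA6 (-3.71 ± 0.12) and IAA5 (-2.50 ± 0.08). All 27 photosystem and Rubisco genes (mean 1.64 ± 0.27, adjusted p = 0.385 with an estimated correlation) and all 21 antenna genes (mean 1.26 ± 0.25, adjusted p = 0.403 with an estimated correlation) rose, RBCS3B by 2.51 ± 0.20 and LHCB4.3 by 1.96 ± 0.21.

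At the preset correlation the shade avoidance list had camera adjusted p = 2.77e-09, the SAUR list camera adjusted p = 1.64e-07, and the auxin list camera adjusted p = 7.4e-07. The photosystem list had camera adjusted p = 3.02e-12, and the antenna list camera adjusted p = 9.63e-09. Counts adjusted over the list alone were the same in these 5 lists. SAUR68, not well above background in PHYBpro, was at least 6.9-fold lower than in phyB-9 (limma adjusted p = 4.88e-10). Of 19 flavonoid and anthocyanin genes 14 rose and 2 fell, with a mean of 1.25 ± 0.11 (camera adjusted p = 2.63e-05, adjusted p = 0.385 with an estimated correlation) and UGT78D2 at 1.95 ± 0.05. In chlorophyll and haem synthesis 19 of 21 genes rose (mean 0.66 ± 0.12, camera adjusted p = 1.26e-06, adjusted p = 0.385 with an estimated correlation) and the fallers were again PORA (-3.56 ± 0.14) and PORB (-0.91 ± 0.08). Of 15 ethylene genes 12 fell (mean -0.87 ± 0.04, camera adjusted p = 8.18e-05, adjusted p = 0.0652 with an estimated correlation), with ACS6, an enzyme gene of ethylene synthesis, at -1.32 ± 0.14. Expansins and xyloglucan endotransglucosylases fell in 14 and rose in 4 of 21 genes (mean -0.93 ± 0.07, camera adjusted p = 0.00789, adjusted p = 0.469 with an estimated correlation), with XTH17 at -3.64 ± 0.09. Starch metabolism genes rose in 12 and fell in 3 of 16 genes (mean 0.63 ± 0.05, camera adjusted p = 0.00545, adjusted p = 0.385 with an estimated correlation), with APL1 at 1.41 ± 0.11. Of 31 photoreceptor and light signalling genes 17 rose and 10 fell (mean 0.46 ± 0.08, camera adjusted p = 0.0326, adjusted p = 0.6 with an estimated correlation), with SPA1 at 1.36 ± 0.04. Adjusted over the list alone, these 6 lists changed only in the photoreceptor list, to 18 rising genes. Scaling all arrays to the same spread ended the calls of the photoreceptor list (mean 0.34, adjusted p = 0.221) and the expansin list (-0.69, 0.0599). It also ended those of PORA (-2.65), PORB (-0.68), SPA1 (1.01), APL1 (1.05) and RBCS3B (1.87). The fit shares its estimate of a gene's spread between the lines, so the spread between the rescaled ML1pro arrays enters the PHYBpro tests too. A PHYBpro call that ended under this scaling therefore need not reflect spread between the PHYBpro arrays. With processed signals the ethylene mean was -1.60.

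Among genes with a symbol the largest rises in PHYBpro were those of BAM3 (4.91 ± 0.12), XTH6 (4.3 ± 0.27), the fructose-bisphosphate aldolase gene FBA5 (3.99 ± 0.12) and PGL5 (3.87 ± 0.31), annotated as a 6-phosphogluconolactonase. CP12-2 (3.74 ± 0.08), a regulator of the Calvin cycle, NDA1 (3.70 ± 0.22), CGLD27 (3.66 ± 0.19), DOT3 (3.59 ± 0.27), the Rubisco assembly chaperone gene RbcX1 (3.58 ± 0.21) and the receptor kinase gene RK2 (3.57 ± 0.23) completed the 10. The largest falls among such genes were those of the pectin methylesterase genes ATPMEPCRD (-4.31 ± 0.10) and PME61 (-3.78 ± 0.12) and of RTFL21 (-4.30 ± 0.17), a gene of the ROTUNDIFOLIA-like peptides. PIL1, SAUR22, IAA19 and IAA6 were among the 10, with GRF7 (-3.75 ± 0.27), the marneral synthase gene MRN1 (-3.69 ± 0.27) and MYB10 (-3.66 ± 0.11).

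In all, 14466 of 20896 genes (69.2%) differed between PHYBpro and phyB-9, 6812 higher and 7654 lower, and 2153 differed by at least 2-fold, 1306 higher and 847 lower. With the scanner software's processed signals 1613 genes were at least 2-fold lower, and scaling all arrays to the same spread gave 7752 called genes, 783 of them at least 2-fold.

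**Figure D2:**
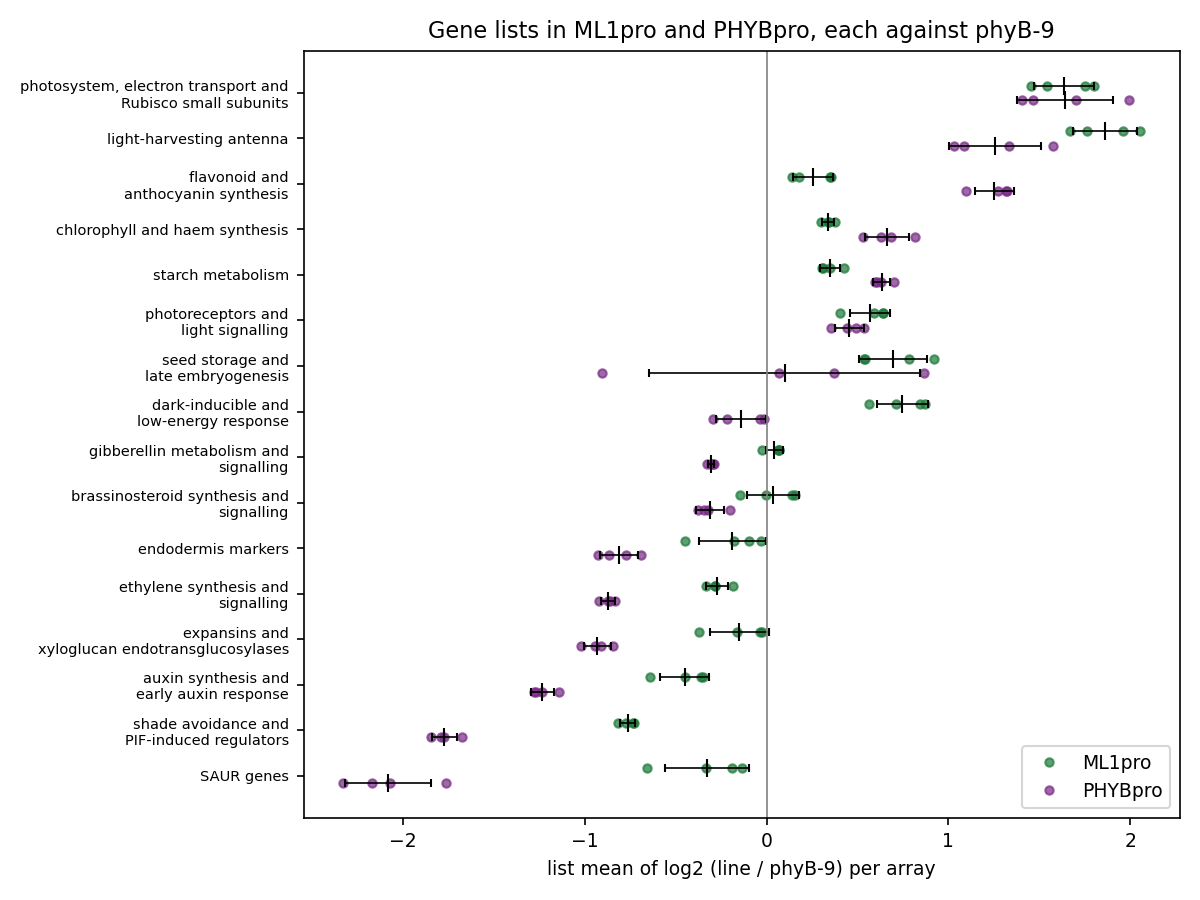
Mean log2 ratio of line over phyB-9 per array (points, 4 per line) for each fixed gene list that passed camera's preset test in ML1pro, in PHYBpro or between the lines, with the mean and SD over arrays as black bars. The antenna list lies higher in ML1pro (21 genes, mean 1.86 ± 0.18) than in PHYBpro (1.26 ± 0.25), while the SAUR list lies at -0.33 ± 0.23 in ML1pro and -2.08 ± 0.24 in PHYBpro.

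Across the 20896 genes the log2 ratios of both lines correlated at Pearson r = 0.782 and Spearman rho = 0.685 (genes are not independent replicates), with a covariance of 0.218 and a slope of ML1pro on PHYBpro of 0.52. As a null, each gene's line mean was subtracted and the signs of the arrays' deviations were turned at random. Over 79 draws the highest absolute r was 0.415 and the highest absolute covariance 0.0042. Subtracting the means also removes a dye bias shared by all arrays, so this null cannot tell such a bias from shared changes. Called in both lines and higher in both were 4151 genes, against 1809.9 for independent lists, and lower in both were 4000, against 1907.3. At 2-fold, 604 genes were higher in both (43.7 for independent lists) and 127 lower in both (5.8). With the scanner software's processed signals 1402 changed at least 2-fold the same way in both, in place of 731, and with all arrays scaled to the same spread 4670 genes were called the same way, in place of 8151. Of the 2153 genes changed at least 2-fold in PHYBpro, 1941 (90.2%) were called the same way in ML1pro, 23 the opposite way, and 189 were not called.

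Genes were also chosen on 2 PHYBpro arrays, at a mean absolute log2 ratio of at least 1, and measured on the other arrays. Their median log2 ratio in ML1pro was 0.544 ± 0.019 of that in PHYBpro (SD over 6 ways to choose the arrays). The ratio was 0.67 ± 0.031 for genes that rose and 0.393 ± 0.01 for genes that fell. Genes chosen on ML1pro arrays had 1.233 ± 0.106 times the ML1pro value in PHYBpro, 1.18 ± 0.14 for risers and 1.633 ± 0.125 for fallers. These SDs reflect only the choice of arrays. The arrays of the other line were all used each time, so the spread between them is not included. RNA of whole seedlings cannot tell a smaller change per cell from a change in fewer cells. Scaling all arrays to the same spread, which removes a difference in size by its construction, gave 1.146 in place of 0.544, with 1.397 for risers and 0.851 for fallers.

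**Figure D3:**
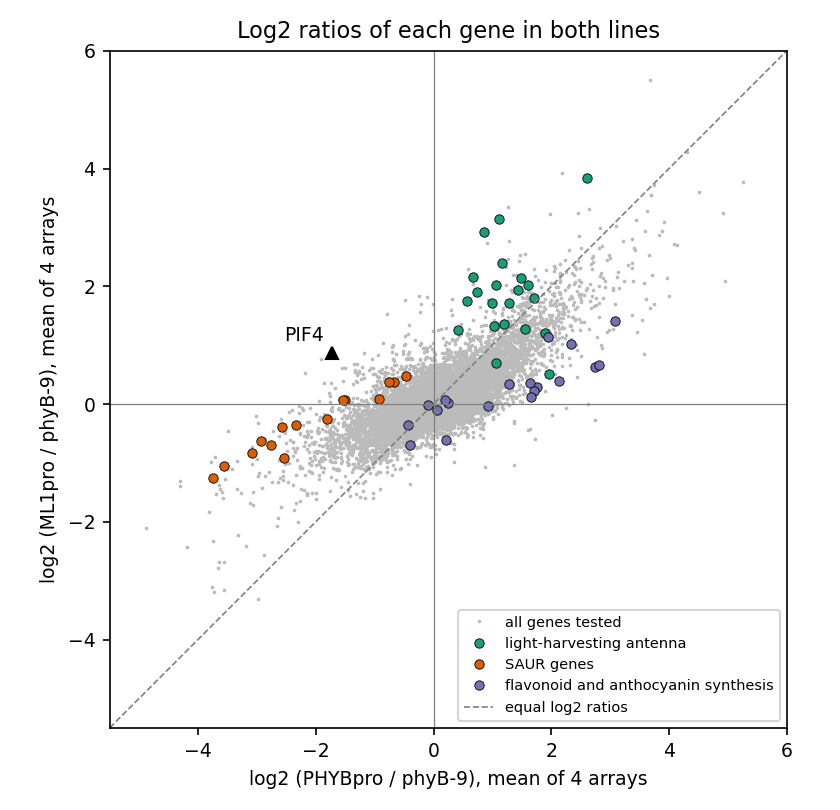
Each point is a gene, with its mean log2 ratio in PHYBpro on the horizontal and in ML1pro on the vertical axis (4 arrays each). Across all genes r is 0.782; the SAUR genes lie above the dashed line of equal ratios and most flavonoid genes below it, and PIF4 lies at -1.73 in PHYBpro and 0.87 in ML1pro.

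The comparison of the lines with each other asks which of these changes differ between the promoters, under which the level of the PHYB transcript differed too. All 15 SAUR genes were higher in ML1pro than in PHYBpro (mean difference of log2 ratios 1.75, adjusted p = 0.223 with an estimated correlation). So were all 17 shade avoidance genes (mean 1.01, adjusted p = 0.0561 with an estimated correlation) and 13 of 23 auxin genes (mean 0.78, 1 lower, adjusted p = 0.223 with an estimated correlation), but the list means fell to 0.07 and 0.06 when all arrays were scaled to the same spread. Flavonoid genes were lower in ML1pro in 13 of 19 (mean -1.0, adjusted p = 0.197 with an estimated correlation), with the flavonol synthase gene FLS1 at -2.15 ± 0.11 (SE). PIF4, which encodes a transcription factor that phytochrome B destabilises, went opposite ways, at 0.87 ± 0.33 in ML1pro and -1.73 ± 0.19 in PHYBpro, and PIF5, of the same family, stood at 1.56 ± 0.20 and -0.23 ± 0.22 (differences 2.59 ± 0.16 and 1.79 ± 0.13, SE). The fall of PIF5 in PHYBpro, seen on 3 of 4 arrays, lay close to the threshold (limma adjusted p = 0.0408), and it was not past it without PHYBpro replicate 1, 2 or 3 or without ML1pro replicate 2, with processed signals (0.0826), with the mean of all probes (0.285) or with all arrays scaled to the same spread (0.798).

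Of the SAUR genes, SAUR68 differed by 2.3 ± 0.09 (SE) in the fit (camera adjusted p = 5.51e-11 for the list). Its PHYBpro level was only a bound, and the fitted difference ranged from 1.3 to 5.1 under other settings. In the shade avoidance list FHL, which carries phytochrome A to the nucleus, differed by 1.46 ± 0.07 (camera adjusted p = 7.18e-10 for the list), and in the auxin list IAA29 by 2.35 ± 0.09 (camera adjusted p = 1.4e-05 for the list). The flavonoid list had camera adjusted p = 6.02e-09. Ethylene genes were higher in ML1pro in 11 of 15 (mean 0.60, 0.26 to 1 under other settings, camera adjusted p = 8.43e-05, adjusted p = 0.0561 with an estimated correlation), with ACS6 at 1.12 ± 0.08. Expansins and xyloglucan endotransglucosylases were higher in 14 and lower in 2 of 21 (mean 0.78, camera adjusted p = 0.000112, adjusted p = 0.293 with an estimated correlation), with XTH17 at 2.26 ± 0.14. Brassinosteroid genes were higher in 8 of 12 (mean 0.35, camera adjusted p = 0.00406, adjusted p = 0.499 with an estimated correlation), with the synthesis gene BR6OX1 at 1.21 ± 0.10. Gibberellin genes were higher in 12 and lower in 2 of 23 (mean 0.35, camera adjusted p = 0.00919, adjusted p = 0.248 with an estimated correlation), with the synthesis gene GA20OX1 at 1.76 ± 0.09. Adjusted over the list alone, the genes higher in ML1pro numbered 15 of the SAUR, 17 of the shade avoidance, 13 of the auxin, 12 of the ethylene, 14 of the expansin, 10 of the brassinosteroid and 13 of the gibberellin list, and those lower in ML1pro 13 of the flavonoid list.

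Within the antenna list 14 of 21 genes were higher in ML1pro and 3 lower, or 15 and 4 adjusted over the list alone (mean 0.61, camera adjusted p = 0.00204, adjusted p = 0.641 with an estimated correlation). LHCB2.2 differed by 2.07 ± 0.16 and LHCB4.3 by -1.45 ± 0.11 (SE). The photosystem and Rubisco list was not called between the lines, with 5 genes lower and 1 higher, and its mean of -0.004, below a median of 0.18 (camera adjusted p = 0.992), turned to 1.31 when all arrays were scaled to the same spread (adjusted p = 0.00127). RBCS3B, at -0.74 ± 0.11, turned to 0.91 under that scaling. Chlorophyll synthesis genes were lower in ML1pro in 13 and higher in 2 of 21 (mean -0.33, camera adjusted p = 0.000381, adjusted p = 0.472 with an estimated correlation), with the chlorophyll synthase gene CHLG at -1.07 ± 0.07, and starch genes lower in 9 and higher in 3 of 16 (mean -0.29, camera adjusted p = 0.00769, adjusted p = 0.293 with an estimated correlation), with the phosphoglucomutase gene PGM at -1.08 ± 0.08, but the means of both lists turned to 0.05 and 0.06 when all arrays were scaled to the same spread. Adjusted over the list alone 14 chlorophyll and 9 starch genes were lower, and 3 and 3 higher. Photoreceptor genes (8 higher, 9 lower, camera adjusted p = 0.808) and clock genes (6 higher, 7 lower, mean 0.17, median -0.02, camera adjusted p = 0.808) went both ways, with the clock genes ELF4 at -1.29 ± 0.06 and PRR7 at 1.15 ± 0.07. The exact permutation test of the arrays' list means gave p = 0.0286, the smallest possible, for each of the 13 lists with a camera call. Scaling all arrays to the same spread ended the calls of the shade avoidance (mean 0.07, adjusted p = 0.521), auxin (0.06, 0.987), expansin (0.31, 0.361), brassinosteroid (0.17, 0.0703), gibberellin (0.25, 0.11) and endodermis lists (0.13, 0.543), and moved the means of the SAUR (0.80), ethylene (0.26), flavonoid (-0.59) and antenna lists (1.96), which stayed called. It also ended the calls of genes whose difference became smaller, FLS1 (-1.04), IAA29 (1.05), ACS6 (0.62), XTH17 (0.21), BR6OX1 (0.69), GA20OX1 (0.86), LHCB4.3 (-0.61) and CHLG (-0.58), and of PIF5 (2.54) and LHCB2.2 (3.93), whose difference became larger.

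Of the genes with a symbol, the highest in ML1pro relative to PHYBpro were RTFL21 (3.00 ± 0.13, SE), ATPMEPCRD (2.92 ± 0.14), IAA6 (2.81 ± 0.11), RTFL1 (2.81 ± 0.14) and PME61 (2.80 ± 0.14). Scaling all arrays to the same spread ended the calls of RTFL21 (0.87), ATPMEPCRD (0.70), IAA6 (1.11) and PME61 (0.97). RTFL1 stood at -0.20 in ML1pro, where it was not called (but called under 4 other settings, adjusted p = 0.0298 to 0.039), and fell by 3.01 in PHYBpro. Lowest in ML1pro were the zinc transporter gene HMA2 (-3.01 ± 0.11), RbcX1 (-2.74 ± 0.15), the early light-induced gene ELIP1 (-2.41 ± 0.18), the chloroplast envelope gene OEP6 (-2.33 ± 0.11) and QQS (-2.31 ± 0.10), a regulator of starch content. HMA2, ELIP1 and OEP6 fell in ML1pro (-0.27, -1.04 and -0.60) and rose in PHYBpro (2.74, 1.36 and 1.73). HMA2 in ML1pro (limma adjusted p = 0.0173) was not called without one of ML1pro replicates 2 to 4.

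In all, 8340 of 20896 genes (39.9%) differed between the lines, 4575 higher and 3765 lower in ML1pro, and 685 by at least 2-fold, 475 higher and 210 lower. Genes called in both lines with opposite directions numbered 649, but 976 without ML1pro replicate 1 and 355 to 378 without one of ML1pro replicates 2 to 4. Scaling all arrays to the same spread gave 377 such genes and left 2056 that differed, 167 of them at least 2-fold, the scanner software's processed signals gave 1118 at least 2-fold, and the Cy5 channel alone 376.

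The phyB-9 channel holds the same genotype on both slides, so it shows how far slide, culture and hybridisation differ without a difference in genotype. Between the ML1pro and the PHYBpro arrays, 681 genes differed in this channel by limma, 249 higher and 432 lower on the ML1pro arrays, 3 of them by at least 2-fold. The line channel differed in 8799 genes. The SD across genes of the difference was 0.147 in phyB-9 and 0.339 in the line channel. Of the 8340 genes that differed between the lines, 6765 (81.1%) were called the same way in the line channel alone and 576 were called in phyB-9. Of the 685 with at least 2-fold differences, these numbers were 680 and 127. The phyB-9 count rested on single arrays, with 3060 genes without ML1pro replicate 1, 51 to 76 without one of ML1pro replicates 2 to 4, and 225, 247 and 185 without PHYBpro replicate 1, 3 or 4.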

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

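The dye bias test on second probes and the counts of splits were planned, and the other tests of explanations in this part were chosen after the results were seen. Of 204 groups of 4 arrays (array summaries, list means and named genes), 13 had 1 array far from the other 3, where chance gives about 1 in 20 groups, and 10 of the 13 were ML1pro replicate 1. On that array the SD of the log2 ratios was 0.368, the gibberellin list mean was -0.03, and the log2 ratios were 1.99 for NDA1, -0.42 for SAUR68, 2.16 for BBX16, -1.65 for MYB10, -1.45 for CML41, -0.33 for bbx23, 1.77 for PGL5 and 1.65 for CGLD27. The other 3 were SPA1 at 1.3 on ML1pro replicate 3, KIN1 at -0.90 on ML1pro replicate 2 and GA2OX6 at -1.55 on PHYBpro replicate 4.

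A candidate explanation for ML1pro replicate 1 is RNA of each channel mixed into the other, since genes that rise on other ML1pro arrays deviated there by 0.317 in Cy3 (replicates 2 to 4: 0.039, 0.013 and -0.053) and genes that fall by 0.208 in Cy5 (-0.031, 0.033 and -0.002) and -0.091 in Cy3 (0, -0.008 and 0.008), while the Cy5 deviation of rising genes, -0.152, was close to that of replicate 2 (-0.101, 0.056 and 0.045). Mixing is not the whole cause: it would lower Cy3 of genes at least 2-fold lower in PHYBpro, yet they deviated by 0.184 (replicates 2 to 4: at most 0.037). An earlier form of this test on genes chosen in PHYBpro gave fallers a Cy5 deviation of 0.08, within the range of replicates 2 to 4 (highest 0.088), and the set was then changed to genes chosen in ML1pro. A weaker response of that array's ML1pro seedlings alone would leave Cy3 as on the other arrays, yet genes at least 2-fold higher in PHYBpro deviated there by 0.102 (replicates 2 to 4: at most 0.027), and a dim hybridisation is excluded by 75.4% of probes well above background in Cy5, the highest of the 8 arrays. Across genes, the deviation from the other arrays among replicates 2 to 4 had an SD of 0.231 in Cy3 on replicate 1 (replicates 2 to 4: 0.075, 0.068 and 0.079). In Cy5 this SD was 0.14 (0.141, 0.114 and 0.121), so the deviation lay mainly in the phyB-9 channel. A different state of the phyB-9 seedlings on that array stays open and was not tested apart from other causes in that channel.

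Small changes were shared by both lines: 6127 genes were called in the same direction in both and stayed under 2-fold. With no dye exchange, a dye bias of single probes could give such calls, but among 1886 of these genes with a second probe 82.1% of second probes had the direction of the first in both lines, against 43.5% with second probes paired at random, which excludes it as the whole cause. The slopes of the second probe's ratio on the first's were 0.66 in ML1pro and 0.73 in PHYBpro, so a part that belongs to single probes stays open. The same phyB-9 extracts on both slides, under the same numbers, would make same-numbered phyB-9 channels correlate. The correlations were 0.16, 0.136 and 0.152 for numbers 1, 2 and 4 and -0.159 for number 3. The last goes against a shared extract for that number, but deviations from a mean of 4 arrays depend on each other. Extracts shared under other numbers could not be seen, so shared extracts stay open. Dye effects on whole transcripts, and the return of phytochrome B to both lines as the biological explanation, were not tested against each other.

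The lines differed in 8340 genes and in 13 lists by tests of the difference itself, ML1pro minus PHYBpro. With an estimated correlation 0 lists were called. The mean differences were 1.01 for shade avoidance, 0.78 for auxin, 1.75 for SAUR, 0.35 for brassinosteroid, 0.35 for gibberellin, 0.60 for ethylene, 0.61 for antenna, 0.78 for expansin, 0.89 for dark-inducible and 0.63 for endodermis genes. They were -1.0 for flavonoid genes, and -0.33 for chlorophyll and -0.29 for starch genes, which turned to 0.05 and 0.06 with all arrays scaled to the same spread. That scaling also ended the calls of the shade avoidance (0.07), auxin (0.06), brassinosteroid (0.17), gibberellin (0.25), expansin (0.31) and endodermis lists (0.13).

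A weaker response in ML1pro by 1 scale factor is excluded as the whole cause, since the ratio of list means, ML1pro over PHYBpro, was 1.482 (SD 0.29 over pairs of arrays) for antenna and 0.431 (SD 0.026) for shade avoidance genes. For the 685 genes at least 2-fold different, the Cy3 channel carried a median of 19.6% of the difference. A difference of phyB-9 between the slides is therefore excluded as their main cause. For the other genes this share was not computed. Of all 8340 genes, 6765 (81.1%) were called the same way in the line channel alone and 576 were called in phyB-9. This argues against phyB-9 as the whole cause for those 6765 genes, while for the rest it stays open. Differences of slide, culture or hybridisation in the line channel cannot be told apart from the promoter, because each line had its own slide. The same holds for the amount of PHYB transcript in whole seedlings, which gives no level per cell and whose log2 ratio differed by -1.39, ML1pro minus PHYBpro. It also holds for other traits of the transgenic lines, since the labels name 1 line per promoter. The promoter stays a possible explanation that was not tested apart from these. For the 8340 genes 1 of the 35 splits of the 8 arrays, the real one, gave as many (highest other 0), which argues against chance. It is the smallest share that 35 splits can give, and mixed splits count a line difference as spread, which lowers their counts. For the 681 genes of phyB-9 the real split alone also gave as many (1 of 35, highest other 47). This too argues against chance, with the same limits, and 4541 of the 20896 genes had an unadjusted limma p under 0.05 in this channel. The size of the phyB-9 count is uncertain, since it ranged from 51 to 3060 with 1 array left out. For the 13 lists 2 of the 35 splits gave as many. The other, with 15, set ML1pro replicate 1 and PHYBpro replicates 2 to 4 against the rest. Such a split still carries part of the difference between the lines, and camera compares a list with other genes. The count of splits therefore cannot tell chance from a line difference for the lists, and chance stays open there.

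For each line against phyB-9 the 4 arrays allow 8 assignments of the channels, too few for a share under 0.05. With missing values filled in, 10760 genes were called in ML1pro and 14468 in PHYBpro, each in 1 of the 8 assignments (highest other 0 in both). The lists called were 10 in ML1pro (2 of 8 assignments gave as many, highest other 11) and 11 in PHYBpro (2 of 8, highest other 11).

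Features that matched no locus were left out of the comparisons. Of 4605 such features tested, 160 changed at least 2-fold in ML1pro and 364 in PHYBpro.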

How the results depend on the processing

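Except for 2 alternatives added after seeing the data (unmatched probes counted, and the effect size without ML1pro replicate 1), the alternatives were planned. The counts ranged over them from 8240 to 12327 in ML1pro, 7752 to 17111 in PHYBpro and 2056 to 9407 between the lines, the highest of each with unmatched probes counted, where more features are tested, and the correlation of the lines from 0.758 to 0.803. The labels state no pairing, and same-numbered arrays were not treated as pairs, since not all 4 correlated (residual correlations of 0.33, 0.06, -0.30 and 0.33 between the lines, both arrays best with their own number only for number 1). A block of these numbers gave 10666, 14414, 8359 and, for phyB-9, 468 genes. A planned run on the authors' values was not run, because their tables hold no values per array. Of 69 list results 45 kept their side and direction under all alternatives, and of 234 gene results 140. Signal over background limits the tests to genes well above background in at least 1 group.

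Equal spread of all arrays, which removes size differences by construction, gave 7752 genes for PHYBpro, 2056 for the difference, 6 lists, an effect ratio of 1.146 and 0.23 for PHYB. The lines share the estimate of a gene's spread, so spread between the rescaled ML1pro arrays also enters the PHYBpro calls under this setting. The differences of called lists that turned were 0.05 (chlorophyll) and 0.06 (starch), and of uncalled lists 1.31 (photosystem, then called), -0.02 (epidermis) and -0.03 (vascular). Those of called genes were -0.96 (CER1), -0.84 (GA2OX6), -0.07 (JAZ1), 0.89 (SPA1), -1.08 (IAA20), -1.05 (MYB10), -0.88 (FAR8), -1.56 (HEC2), -0.84 (CML41), -1.81 (XTH15), 0.95 (BAM3), -0.47 (XCP1), 0.33 (UGT78D2), 0.82 (APL1), -1.55 (FAR1), 1.12 (PGL5), 0.91 (RBCS3B), -0.45 (GRF7), -2.45 (PORA) and 0.81 (CGLD27), and of uncalled genes 1.98 (NDA1), 2.3 (MSRB6), 1.01 (DOT3), 2.95 (XTH6), -0.13 (bbx23) and 0.32 (COP1).

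The effect ratio of 0.544 was 0.609 without background subtraction, 0.612 with processed signals, 0.483 and 0.584 with genes chosen at 0.58 and 1.5, and 0.576 without ML1pro replicate 1. The 681 phyB-9 genes became 398 without background subtraction and 423 with quantile normalization of Cy3 alone, and ranged from 51 to 3060 with 1 array left out. The NDA1 difference of -0.15 also turned, to 0.32 without background subtraction, and ranged from -0.36 to 0.37 with 1 array left out (0.37 without ML1pro replicate 1), and EFE in PHYBpro from -0.01 to 0.24 with median centring and 0.31 with the mean of all probes. For these values the cause was not tested.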

Other observations

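The list tests in this part were planned, and the comparison with the authors' tables was chosen after the values were seen. Dark-inducible and low-energy genes rose in ML1pro in 5 and fell in 1 of 7 genes, with a mean log2 ratio of 0.75 ± 0.14 (SD over arrays, n = 4, camera adjusted p = 0.0165, adjusted p = 0.459 with an estimated correlation), and had no camera call in PHYBpro (mean -0.14 ± 0.14, 1 rose and 3 fell, camera adjusted p = 0.696, fry adjusted p = 0.00566). ASN1, an asparagine synthetase gene that darkness induces, rose by 1.70 ± 0.20 in ML1pro, where the list call ended when all arrays were scaled to the same spread (adjusted p = 0.0655) while its mean grew to 1.09. Between the lines 6 of the genes were higher in ML1pro, or 7 adjusted over the list alone (mean 0.89, camera adjusted p = 0.000196, adjusted p = 0.223 with an estimated correlation), with ASN1 at 1.71 ± 0.11 (SE), which under that scaling became 2.71 and lost its call (adjusted p = 0.112). Seed storage and late embryogenesis genes rose in 6 of 12 in ML1pro (mean 0.70 ± 0.19, camera adjusted p = 0.0331, adjusted p = 0.781 with an estimated correlation), but without ML1pro replicate 1 or 2 the list was not called (means 0.67 and 0.62, adjusted p = 0.1 and 0.0682), and fry did not call it with all arrays (adjusted p = 0.0774). CRA1, a storage globulin gene, rose by 1.81 ± 0.73 there, and lost its call at 3.44 with all arrays scaled to the same spread (adjusted p = 0.052). In PHYBpro 4 rose and 3 fell (mean 0.10 ± 0.74, camera adjusted p = 0.766), and the mean was 0.01, -0.15 and 0.43 without PHYBpro replicate 1, 3 and 4. Between the lines 5 were higher in ML1pro (mean 0.60, 0.26 without PHYBpro replicate 4, camera adjusted p = 0.35). Clock and flowering genes went both ways, 10 up and 6 down of 18 in ML1pro (mean 0.61 ± 0.12, camera adjusted p = 0.323) and 10 and 7 in PHYBpro (mean 0.44 ± 0.06, camera adjusted p = 0.234), where fry gave adjusted p = 0.00016 and 0.000127, with the clock gene LNK2 at 2.74 ± 0.29 in ML1pro. Defence, jasmonate and abiotic stress genes had no camera call in any comparison (means 0.29 ± 0.14 in ML1pro and 0.05 ± 0.05 in PHYBpro, camera adjusted p = 0.588 and camera adjusted p = 0.696, fry adjusted p = 0.115 and 0.00315), although JAZ1, a repressor of jasmonate responses, fell in PHYBpro at -1.45 ± 0.05, and the cold-induced gene KIN1 fell in ML1pro at -1.03 ± 0.09. Between the lines 8 of 14 defence genes were higher in ML1pro and 4 lower (camera adjusted p = 0.407).

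Epidermis markers had no camera call in ML1pro (mean -0.04 ± 0.14, 3 rose and 4 fell of 12, camera adjusted p = 0.954), in PHYBpro (mean -0.23 ± 0.18, camera adjusted p = 0.627, fry adjusted p = 0.012) or between the lines (camera adjusted p = 0.35), while CER1, a gene of cuticular wax synthesis, fell in both lines, at -1.64 ± 0.11 and -2.27 ± 0.11, the second without a call at -1.69 when all arrays were scaled to the same spread (adjusted p = 0.076). Endodermis markers were higher in ML1pro than in PHYBpro in 4 of 5 (mean 0.63, camera adjusted p = 0.0187, adjusted p = 0.418 with an estimated correlation), with CASP2, a gene of the Casparian strip, at 1.25 ± 0.14 (SE), and scaling all arrays to the same spread ended that call (mean 0.13, adjusted p = 0.543) and the call of CASP2 (0.62, 0.371). They had no camera call against phyB-9 (means -0.19 ± 0.18 and -0.81 ± 0.11, camera adjusted p = 0.494 and camera adjusted p = 0.0558, fry adjusted p = 0.0969 and 6.47e-05, mean -0.10 in ML1pro without its replicate 1), but in PHYBpro camera called the list under 6 other settings (adjusted p = 0.0155 to 0.0489). Vascular markers (means -0.16 ± 0.12 and -0.44 ± 0.05, camera adjusted p = 0.588 and camera adjusted p = 0.252, camera adjusted p = 0.113 between the lines) and root hair markers (means -0.38 ± 0.19 and -0.06 ± 0.24, camera adjusted p = 0.0695 and camera adjusted p = 0.871, camera adjusted p = 0.125 between the lines) had no camera call. By fry the vascular list passed in PHYBpro (adjusted p = 0.000317) and between the lines (0.0116, exact permutation adjusted p = 0.047), and the root hair list in ML1pro (0.0174). XCP1, a protease gene of xylem vessels, fell in both lines, at -0.71 ± 0.19 and -1.13 ± 0.04, the second without a call at -0.84 under equal spread (adjusted p = 0.161). Gravitropism and auxin transport genes had no camera or fry call (means 0.11 ± 0.13 and 0.07 ± 0.04, camera adjusted p = 0.494 and camera adjusted p = 0.961, camera adjusted p = 0.808 between the lines), with LZY1 at 0.64 ± 0.33 and 1.29 ± 0.02. Brassinosteroid genes (means 0.04 ± 0.14 and -0.31 ± 0.08, camera adjusted p = 0.954 and camera adjusted p = 0.0614) and gibberellin genes (means 0.04 ± 0.05 and -0.30 ± 0.02, camera adjusted p = 0.619 and camera adjusted p = 0.0715) had no camera call against phyB-9, while fry gave adjusted p = 0.00148 for brassinosteroid in PHYBpro and 0.0128 and 4.07e-06 for gibberellin genes in ML1pro and PHYBpro. The gibberellin 2-oxidase gene GA2OX6 fell in both lines, at -1.30 ± 0.03 and -1.66 ± 0.07, the second without a call at -1.23 under equal spread (adjusted p = 0.0896). Under some settings camera called other lists that it did not call here, in ML1pro those of the clock (0.0488) and root hairs (0.0208 to 0.0407), in PHYBpro those of brassinosteroid (0.0327 to 0.041) and gibberellin (0.0376), and between the lines those of vascular (0.0409), root hair (0.0278 and 0.0434) and seed genes (0.0425). The brassinosteroid median in ML1pro was -0.05 against that mean of 0.04 ± 0.14, and camera's direction for the gibberellin list there was down against its mean of 0.04 ± 0.05. Reference genes had no camera or fry call (means 0.10 ± 0.09 and -0.02 ± 0.10, camera adjusted p = 0.619 and camera adjusted p = 0.916, camera adjusted p = 0.671 between the lines).

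In the authors' deposited table for ML1pro, a regression of its log2 ratios on the ratios of single arrays computed here gave weights of -0.001, 0.333, 0.334 and 0.334 for replicates 1 to 4, and the table's ratios differed from the mean of replicates 2 to 4 with an SD of 0.017 and from the mean of all 4 with 0.063. In the authors' deposited table for PHYBpro the weights were 0.25, 0.249, 0.249 and 0.252. Across spots the tables' ratios correlated with those computed here at r = 0.991 and 0.999. PHYB stood at 1.82 and 3.09 in the authors' deposited tables. At a false discovery rate under 0.05 the authors' deposited tables hold 18827 (ML1pro) and 21625 (PHYBpro) of 43803 spots.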
